A study of Mus musculus with 10 samples.

How the data were processed

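The series measured single-cell RNA in mouse salivary glands, the parotid gland (PG) and the submandibular gland (SMG), with droplet-based 3' libraries in which each molecule carries a unique molecular identifier (UMI). There were 10 libraries in 10 groups, 1 library per group, so no group had a replicate. Of these, 4 libraries came from embryonic day 13 (E13) tissue separated into epithelium and mesenchyme, which gave PG epithelium, PG mesenchyme, SMG epithelium and SMG mesenchyme. The other 6 came from E13 glands cultured for 6 days, namely PG and SMG control cultures, each with and without Dispase (the protease used to part epithelium from mesenchyme), and the recombined cultures of PG epithelium with SMG mesenchyme and of SMG epithelium with PG mesenchyme. The labels of the recombined cultures do not state their protease treatment. They were coded as Dispase-treated, because their tissues had been parted, and the results under other codings are in the closing section.

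For the cultured libraries, per the submitters' processing notes, the tools were Cell Ranger 6.1.1 and Seurat 4 with genome build GRCm38, and the deposited gene by barcode matrices list 32285 genes. For the E13 libraries the notes name Cell Ranger 2.1.1 and Seurat 3 with the same build, and the deposited matrices list 27998 genes. Cells were released with Accutase or Accumax from the cultures and with a protease active in the cold from the E13 tissue, per the labels' protocols. The values in the deposited matrices are raw UMI counts per gene and barcode, without normalization by the authors, and the authors' cell annotation was not used here. E13 and cultured libraries differed in tissue handling, kit and gene list and were never tested against each other. Totals per library ran from 26552144 to 59712409 UMIs and barcodes per library from 3304 to 16496.

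Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. The mitochondrial limit removed unequal shares of the cultured libraries. It took 54.4% of barcodes from the PG control without Dispase, 53.8% from PG epithelium with SMG mesenchyme, 59.95% from SMG epithelium with PG mesenchyme and 40.1% from the SMG control without Dispase, against 6.49% and 16.4% from the PG and SMG controls with Dispase. Doublets were scored per library with Scrublet as written in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 cells. Clustering, separately for the cultured and the E13 libraries, used 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2), with no alignment of libraries. A cluster was called X-like where at least 3 markers of that class were each found in at least 25% of its cells. The marker lists were fixed before the data were examined. A class's score was the mean of its markers' expression scaled from 0 to 1 across clusters. It had to lead by at least 0.2 the score of every other class with at least 3 markers so found. Classes with fewer such markers were not weighed. Shallow clusters and clusters led by genes of another kind stayed unnamed. Shares of cells are given with exact Clopper-Pearson 95% binomial intervals, which cover counting error only, and a share of 0 with the limit that 3 counts of the total would give.

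UMI counts of the epithelial-like and of the mesenchymal-like cells were summed per library, and CPM, each gene's counts scaled to a common library total, were taken over each sum. The authors' raw counts were thus tested as sums per library and never as single cells. Genes passed a filter on low counts (edgeR filterByExpr). The test was edgeR 4.0.16's quasi-likelihood F-test in R 4.3.3, with TMM scaling and Benjamini-Hochberg adjustment at 5% over all genes tested. Control cultures (4 libraries) were fitted with gland and Dispase. All 6 cultured libraries were fitted with epithelium of origin, mesenchyme of origin and Dispase, and once more with the interaction of both origins. Differences are SMG minus PG and treated minus untreated, and a positive interaction means fitted higher in control than in recombined cultures once the Dispase term is taken off. The interaction is the sum of the log2 differences of both controls from both recombined cultures, so it is not the log2 of a single fold difference. These fits leave 1 or 2 residual degrees of freedom, and with 1 library per condition their p-values measure only the spread between these libraries, which may be technical.

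Comparisons of 1 library with 1 library (PG against SMG at E13, and each recombined culture against the Dispase-treated control of the same epithelium or mesenchyme) have no test. They are given as ratios of CPM with exact 95% intervals from the counts, which cover counting error only, and log2 ratios used a pseudocount of 1 CPM. A gene at 0 counts in a whole group is given as an at-least fold against 3 counts over that group. How much of the gland difference a recombined culture showed was taken over genes at least 2-fold apart, with the whole interval, between the controls without Dispase, as the median change from the Dispase-treated control of the same gland over the median difference between the Dispase-treated controls. Its interval came from 200 Poisson draws of the counts. It is 0 where the culture equals its Dispase-treated control and 1 where it has moved by that whole difference.

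The rule for named genes was fixed with those markers, as were the gene lists, the tests and the first group of alternatives given further on. In a tested comparison they are, per direction, the 10 largest log2 changes past the threshold with a mean of at least 20 CPM on the higher side and the same direction in every pair of libraries that differ in that factor alone. Between single libraries they are, per direction, the 10 with the largest lower bound of the ratio and at least 20 CPM in the higher library. In both, a gene's CPM in the class had to reach 0.5 of that in every other named class of that library. Only classes of at least 50 cells counted, so RNA of unnamed clusters and of smaller classes was not guarded against. Predicted genes named Gm or Rik, mitochondrial, ribosomal protein and haemoglobin genes, Xist and Y-linked genes were left out, and members of the fixed lists could be named in any comparison. Of the genes that the rule names, 1 is not reported here. Genes carry the symbols that the files pair with Ensembl identifiers, and positions are from GENCODE vM21 on GRCm38.

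The 26 fixed lists were SMG and sublingual secretory, parotid secretory, acinar secretory machinery, mucous, ductal, basal and myoepithelial, end bud and progenitor, FGF and ERK response, WNT response, Hedgehog response, BMP and TGF-beta response, retinoic acid pathway, Notch pathway, ERBB pathway, mesenchymal ligands and modulators, mesenchymal patterning transcription factors, epithelial transcription factors, extracellular matrix and basement membrane, smooth muscle and myofibroblast, adipogenic and osteochondrogenic, cell cycle, hypoxia and glycolysis, interferon response, dissociation and heat shock, blood and immune RNA, and neuronal and glial RNA. The secretory lists share Bpifa2, Prol1 and Car6. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone, and the median log2 change was set against 10000 random lists of the same size matched on mean expression, as a description of these libraries.

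The scripts were tested on simulated counts drawn from the means and library sizes of the real genes. In the fit for mesenchyme of origin in epithelium, 93% of 100 genes changed 4-fold and 100% of those changed 16-fold were recovered. The interaction fit recovered 6% and 66% of them in epithelium and 2% and 69% in mesenchyme. The fit of control mesenchyme recovered 72% of genes changed 4-fold and called 10 unchanged genes. The fit for mesenchyme of origin in epithelium also called 8 unchanged genes. Every gene was drawn at the same dispersion (spread beyond counting error) of 0.1, where the common dispersion of that real fit was 0.139. Only genes of at least 20 CPM were changed, so these percentages do not give the recovery in the real data. The exact intervals held the true ratio for 97.5% of changed genes, and a simulated share of 0.4 of the gland difference came out as 0.377. The list percentile was tested on normally distributed values rather than counts. Of lists without a shift 8% lay outside the 2.5th to 97.5th percentile. Of lists shifted by 1 on the log2 scale 89% lay above the 97.5th. Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, gland alone, no Dispase term, no doublet removal, a stricter cell filter (2000 UMIs, 1000 genes, 5% mitochondrial), classes assigned per cell, clustering at resolution 0.5, a pseudocount of 10, TMM scaling of ratios and each library left out. The mitochondrial limits of 20% and 50%, the cultured clusters led by Col9a1 taken into epithelium, a term that sets the Dispase-treated controls apart from the other 4 libraries, TMM scaling of the shares, and the controls without Dispase as comparators were added after the data were seen.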

Results

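The series asks how the parotid gland (PG) and the submandibular gland (SMG) of the mouse embryo differ, and which tissue a gland's features follow when the epithelium of 1 gland is grown with the mesenchyme of the other. The libraries of embryonic day 13 (E13) epithelium held 45199132 UMIs for PG and 39162580 for SMG. Those of mesenchyme held 26552144 for PG and 33315643 for SMG. The control cultures held 55660056 UMIs for the PG control without Dispase, 50406843 for the PG control with Dispase, 59594908 for the SMG control without Dispase and 59712409 for the SMG control with Dispase. The recombined cultures held 43750106 for PG epithelium with SMG mesenchyme and 41347669 for SMG epithelium with PG mesenchyme. After the cell filters and doublet removal, between 1786 and 9878 cells per library were left. Every condition was 1 library.

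Epithelial-like and mesenchymal-like cells made up most of the named cells of each culture. Epithelial-like cells were 34.6% (95% interval 32.7 to 36.6%) of the PG control without Dispase, 28.9% of the PG control with Dispase, 50.9% of the SMG control without Dispase and 63.3% of the SMG control with Dispase. In the recombined cultures they were 47.5% of PG epithelium with SMG mesenchyme and 40.7% of SMG epithelium with PG mesenchyme. Neuronal-like cells, which expressed peripherin and the neuronal tubulin Tubb3, were found where SMG mesenchyme was present. They were 0.793% (0.553 to 1.10%) of the SMG control without Dispase, 0.598% (0.438 to 0.796%) of the SMG control with Dispase and 0.668% (0.382 to 1.08%) of PG epithelium with SMG mesenchyme. The PG controls held 2 of 2363 and 2 of 9764 such cells, and there were 0 of 1786 cells in SMG epithelium with PG mesenchyme, which allows a share of up to 0.168% (3 counts of the total). At E13 the same class held 77 of 9878 cells of SMG mesenchyme and 0 of 7572 cells of PG mesenchyme, which allows up to 0.0396% on the same bound. Immune-like cells, led by macrophage genes such as Lyz2 and C1qa, were 6.94% and 5.24% of the PG controls without and with Dispase. They were 1.93%, 0.598%, 0.751% and 1.01% of the SMG control without Dispase, the SMG control with Dispase, PG epithelium with SMG mesenchyme and SMG epithelium with PG mesenchyme. An unnamed cluster led by the neutrophil genes S100a8 and S100a9, found mainly in the SMG control without Dispase, is not counted in these shares. The order of the glands thus holds only for the named class. Shares of cells rest on what survived dissociation and the mitochondrial limit, which removed 6.49% to 59.95% of the barcodes of a cultured library. At a limit of 20% the epithelial-like UMIs of the PG control without Dispase were 19339056 instead of 6287826. Those of the SMG control without Dispase were 34002442 instead of 15994969. They were 20288794 instead of 8467752 in PG epithelium with SMG mesenchyme and 18606563 instead of 6334587 in SMG epithelium with PG mesenchyme. The PG and SMG controls with Dispase changed little, to 19920188 and 38198526 from 18152177 and 36715717. Unnamed cells were 41.5% of the PG control with Dispase, mainly 1 cluster of shallow cells, and 10.5% to 19.6% of the other cultures. Clusters that scored best as epithelial but were led by Col9a1 also stayed unnamed. With them the epithelial-like cells would number 6000 instead of 4874 in the SMG control with Dispase. In the PG control with Dispase they would number 3453 instead of 2820, with smaller changes elsewhere.

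Among the genes named here in E13 epithelium, the glands differed most in Foxa1, a pioneer transcription factor of foregut epithelia. It stood at 48.8 CPM in SMG and 1.51 CPM in PG, a 32.4-fold difference (95% counting interval 25.1 to 42.4). Foxa1 lies on chromosome 12 at 57540628 to 57546916. SMG epithelium was also higher in Aldh1a7, an aldehyde dehydrogenase (18.1-fold, 15.2 to 21.7), and Dlk1, a Notch ligand-like membrane protein (16.5-fold, 15.6 to 17.5). The keratin Krt23 (12.6-fold) and the tight junction claudin Cldn10 (11.03-fold) were higher there too. PG epithelium was higher in Igfbp3, an IGF-binding protein (11.6-fold, 10.6 to 12.7), Foxp2, a forkhead transcription factor (10.7-fold, 8.47 to 13.7), and Ndufa4l2, a mitochondrial protein induced by low oxygen (7.56-fold). Also higher in PG were Sp5, a target of WNT signalling (5.96-fold, 5.24 to 6.80), and Cyp26a1, which breaks down retinoic acid (5.63-fold, 4.78 to 6.67). Of the lists, ductal genes had a median log2 ratio (SMG over PG) of 0.90 and basal and myoepithelial genes one of 0.73, both above all of 10000 random lists. The medians of the WNT response list (-0.52) and of the hypoxia and glycolysis list (-0.63) lay below all of them. The Notch pathway list stood at 0.43 (percentile 99.96) and the Hedgehog response list at -0.46 (percentile 0.25). The difference has no replicate check, and its intervals cover counting error only. Clusters 2 and 4 held most epithelial-like cells of PG where clusters 5 and 7 held most of those of SMG.

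In E13 mesenchyme each gland was higher in some patterning genes. SMG mesenchyme was higher in Nr5a2, an orphan nuclear receptor (69.0 CPM and none counted in PG, at least 334.8-fold with 3 counts as the floor), and the prolactin receptor Prlr (at least 179.8-fold). Also higher there were Fmo1, a flavin monooxygenase (211-fold, 90.4 to 652), and the homeobox genes Alx4 (80.3-fold, 36.7 to 219.5) and Gsc (54.3-fold, 32.8 to 97.3). PG mesenchyme was higher in the chemokine Cxcl14 (208 CPM and none counted in SMG, at least 1685-fold), Gria2, a glutamate receptor subunit (818-fold, 376 to 2232), the homeobox gene Meox2 (579-fold, 281 to 1442) and Pou3f3, a POU-domain transcription factor with 2 counts in SMG (557-fold, 154 to 4611). Among list members, PG mesenchyme was higher in the T-box gene Tbx18 (46.1-fold, 12.1 against 558 CPM), the LIM homeobox gene Lhx8 (46.8-fold), Dlx5 (31.3-fold) and the ligand gene Wnt2 (25.5-fold). The cell cycle list had a median log2 ratio of -1.55 and the blood and immune RNA list one of -2.37, both lower than in all random lists. The patterning transcription factors stood at 0.51, above all of them. The ERBB pathway list, which holds growth factor ligands and their receptors, stood at -0.97 (percentile 0.06). These are 1 library against 1. Most mesenchymal-like cells were in clusters 1 and 6 for PG and in clusters 0, 3, 8, 10 and 12 for SMG.

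**Figure D1:**
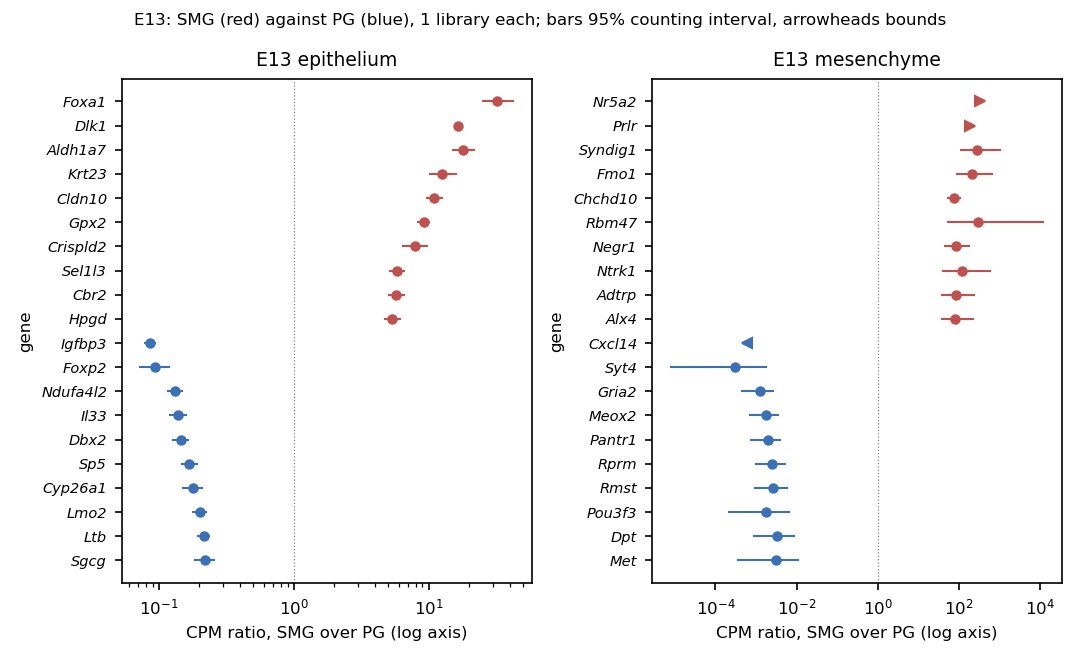
Ratio of CPM in SMG over PG (log axis) in E13 epithelium (left) and E13 mesenchyme (right) for genes named by the fixed rule. Genes higher in SMG are red and genes higher in PG blue, with bars for 95% counting intervals and arrowheads for at-least folds. Foxa1 is 32.4-fold higher in SMG epithelium, and in mesenchyme the differences reach at least 334.8-fold for Nr5a2 and at least 1685-fold for Cxcl14.

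In the control cultures, several of the genes higher in SMG epithelium were secretory. Counts were summed over all epithelial-like cells, so unlike shares of secretory (proacinar-like) cells were not parted from differences within cells. Smgc, the secretory protein C of the developing SMG (chromosome 15, 91838265 to 91861438), was at 143 and 5860 CPM in the SMG controls without and with Dispase and at 0 and 1.27 CPM in the PG controls, a log2 difference of 12.39 (SE 0.45). Bpifa2, the salivary secretory protein first described in parotid (10.40, SE 0.53), the protease inhibitors Wfdc12 (9.38, SE 0.73) and Spink5 (7.13, SE 0.47), the gel-forming mucin Muc19 (7.93, SE 0.43), Ndufa4l2 (7.79, SE 0.38) and the metalloreductase Steap1 (6.41, SE 0.34) were higher too. So was the homeobox gene Tlx1 (chromosome 19, 45150680 to 45156943), at 25.9 and 49.5 CPM in SMG and with no counts in PG (at least 345.1-fold). The trypsinogen genes Try5 (at least 525.9-fold) and Prss2 (6.96, SE 0.46) are near-identical family members, and Smgc overlaps Muc19. Muc19 was at 216 CPM in the SMG control with Dispase but at 0.63 CPM in that without, below the 0.99 CPM of the PG control with Dispase, so its difference rests on 1 library. Each value of these overlapping or near-identical genes is uncertain as to which gene the reads came from. Bpifa2, Wfdc12 and Prss2 were also far lower in the SMG control without Dispase than in that with it. Try5 and Spink5 were at like levels in both. PG epithelium was higher in the long noncoding RNA BC037156 (-10.46, SE 0.50, with 2 counts in SMG), the prostaglandin receptor Ptger3 (-4.97, SE 0.39) and Alkal2, a ligand of the ALK receptor (-2.88, SE 0.26). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 13 genes were higher in SMG and 4 higher in PG of 13793 tested. The adjusted p of edgeR's quasi-likelihood test (Benjamini-Hochberg) ran from 0.00726 for Smgc to 0.0490 for Wfdc12 and Alkal2 and the same direction in 2 of 2 pairs of libraries.

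By list, 14 of 17 hypoxia and glycolysis genes rose in SMG control epithelium adjusted over the list alone and none over all genes tested, with a median log2 difference of 1.25, above all random lists. They include the glucose transporter Slc2a1 (1.79) and the glycolytic enzyme Pgk1 (1.47). Of 20 genes of the acinar secretory machinery 7 rose adjusted over the list alone and none over all genes tested (median 1.47), among them the water channel Aqp5 (2.26) and the chaperone Hspa5 (2.21). Of 14 WNT response genes 4 fell adjusted over the list alone (median -1.21), among them the receptor Lgr5 (-3.19) and the feedback inhibitors Axin2 (-2.52) and Nkd2 (-1.83). Of 12 BMP and TGF-beta response genes 2 fell adjusted over the list alone (median -1.05). Of 16 dissociation and heat shock genes 8 fell on that adjustment (median -0.77), among them Fos (-2.42). The extracellular matrix and basement membrane list, RNA that mesenchymal cells make in abundance, had a median of -0.69 with no member past either threshold. With gland as the only term 0 genes passed edgeR's quasi-likelihood test, 1103 had an unadjusted p under 0.05, and DESeq2's Wald test of the full design passed 471. Without 1 library the fit with gland alone gave 0 (PG control without Dispase), 0 (PG control with Dispase), 1434 (SMG control with Dispase) and 418 (SMG control without Dispase). Epithelial-like cells fell mostly into clusters 12, 15 and 21 in the SMG control without Dispase, led by the stress keratin Krt6a and the lectin Lgals3. They fell into clusters 8, 10, 6, 22 and 7 in the SMG control with Dispase, and into clusters 3, 5, 6, 7 and 16 in the PG controls.

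In control mesenchyme several patterning genes that were higher in PG at E13 were higher in PG again. Pou3f3 (chromosome 1, 42695768 to 42703176) was at 52.6 and 51.5 CPM in the PG controls without and with Dispase and had no counts in SMG (at least 248.2-fold). So did its neighbour Pantr1, a noncoding RNA on the opposite strand that does not overlap it (at least 307.5-fold). Dlx5, a homeobox gene of the jaw (-5.36, SE 0.47), Tbx18 (-4.05, SE 0.32), Wnt2 (-4.07, SE 0.48), Meox2 (-3.89, SE 0.42) and the neurofilament genes Nefm (-5.89) and Nefl (-5.68) were also higher in PG. Nefl lies within the span of Nefm on chromosome 14 but on the opposite strand, and how their reads were split was not checked. SMG mesenchyme was higher in Gsc, a homeobox gene named for the goosecoid organizer gene (3.28, SE 0.31), and Derl3, which helps degrade misfolded proteins (8.30, SE 0.86). It was also higher in the glutathione transferase Gsta2 (4.39, SE 0.45), Ndufa4l2 (3.11, SE 0.33) and the receptor gene P2ry14 (3.50). Derl3, of the acinar secretory machinery list, was at 49.7 CPM in the SMG control without Dispase but at 2.77 CPM in that with it. The size of its difference thus leans on 1 library. In SMG mesenchyme grown with PG epithelium it was at 0.58 CPM. Of 42 measured patterning factors 1 rose and 6 fell over all genes tested, and 4 rose and 9 fell adjusted over the list alone, with Shox2 at -3.17 and Tbx15 at -2.73. Of 42 mesenchymal ligands 4 fell over all genes tested, and 1 rose and 9 fell adjusted over the list alone, among them Wnt5a (-2.79) and the WNT inhibitor Dkk2 (-3.46). Of 11 smooth muscle genes 1 fell over all genes tested (Actg2, -2.26) and 7 fell adjusted over the list alone. Of 16 hypoxia and glycolysis genes 1 rose over all genes tested (Ndrg1, 2.65), and 9 rose and 1 fell adjusted over the list alone, with a median of 1.04.

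With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 26 genes were higher in SMG and 63 in PG of 13380 tested in control mesenchyme. By that edgeR quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.00156 for Pou3f3 and Tbx18 and 0.00337 for Gsc, each in 2 of 2 pairs. Smgc, an epithelial gene, also passed (13.17). The macrophage gene Lyz2 fell (-2.11) where cells named immune-like were fewer, a class that leaves out the unnamed cluster led by neutrophil genes. With gland as the only term 0 genes passed edgeR's quasi-likelihood test, 729 had an unadjusted p under 0.05, and DESeq2's Wald test of the full design passed 215. Without 1 library the fit with gland alone gave 2 (PG control without Dispase), 2 (PG control with Dispase), 1004 (SMG control with Dispase) and 132 (SMG control without Dispase). Mesenchymal-like cells were mostly in cluster 9, led by Ccl2, Mmp3 and Saa3, in the SMG control without Dispase. They were in cluster 2 in the SMG control with Dispase and in clusters 1 and 4 in the PG controls.

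Among the 6 cultures, a small set of genes in mesenchymal-like cells followed the gland that the mesenchyme came from. Pou3f3 was at 68.9 CPM in PG mesenchyme grown with SMG epithelium and at 0.14 CPM in SMG mesenchyme grown with PG epithelium. Its log2 difference by mesenchyme of origin was -9.81 (SE 0.62, 1 count on the low side). Higher with PG origin in the same way were Pantr1 (-10.40, SE 0.63, 1 count on the low side), Nefl (-7.68, SE 0.44), Nefm (-7.16, SE 0.48) and Dlx5 (-5.89, SE 0.40). The same held for Tbx18 (-4.55, SE 0.30; chromosome 9, 87702800 to 87731260), Wnt2 (-4.49, SE 0.45), the growth cone protein Gap43 (-3.81, SE 0.30) and Shox2, a limb and heart homeobox gene (-3.35, SE 0.34). SMG origin was higher in Fndc3c1, a fibronectin domain protein (4.10, SE 0.44), Gsc (3.55, SE 0.30; chromosome 12, 104471209 to 104473330) and P2ry14 (2.996, SE 0.34). Of 43 patterning factors 1 rose and 3 fell over all genes tested, and 4 rose and 11 fell adjusted over the list alone, including Hand2 (1.90) and Tbx15 (-3.22). Of 42 mesenchymal ligands 1 fell over all genes tested, and 2 rose and 4 fell adjusted over the list alone, with the guidance cue Sema3a at 2.04 and the WNT agonist Rspo3 at 1.63.

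edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed these 3 genes with SMG origin and 10 with PG origin among 13565 tested. Its edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.00294 for Pou3f3 and 0.00942 for Gsc and the same direction in 2 of 2 pairs of libraries. Without 1 library the count was 129 (PG epithelium with SMG mesenchyme), 6 (PG control without Dispase) and 193 (PG control with Dispase). It was 35 (SMG control with Dispase), 29 (SMG epithelium with PG mesenchyme) and 6 (SMG control without Dispase). DESeq2's Wald test passed 190 genes. Without the Dispase term 0 genes passed with SMG origin and 7 with PG origin, with a term for the Dispase-treated controls 1 and 6, and under the stricter cell filter 1 and 7. Without either control that had no Dispase they were 0 and 6. The calls with SMG origin thus depend on the Dispase coding, which the labels of the recombined cultures do not state, on the cell filter and on single libraries. Most mesenchymal-like cells were in cluster 19 for PG epithelium with SMG mesenchyme and in clusters 4, 17 and 1 for SMG epithelium with PG mesenchyme.

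**Figure D2:**
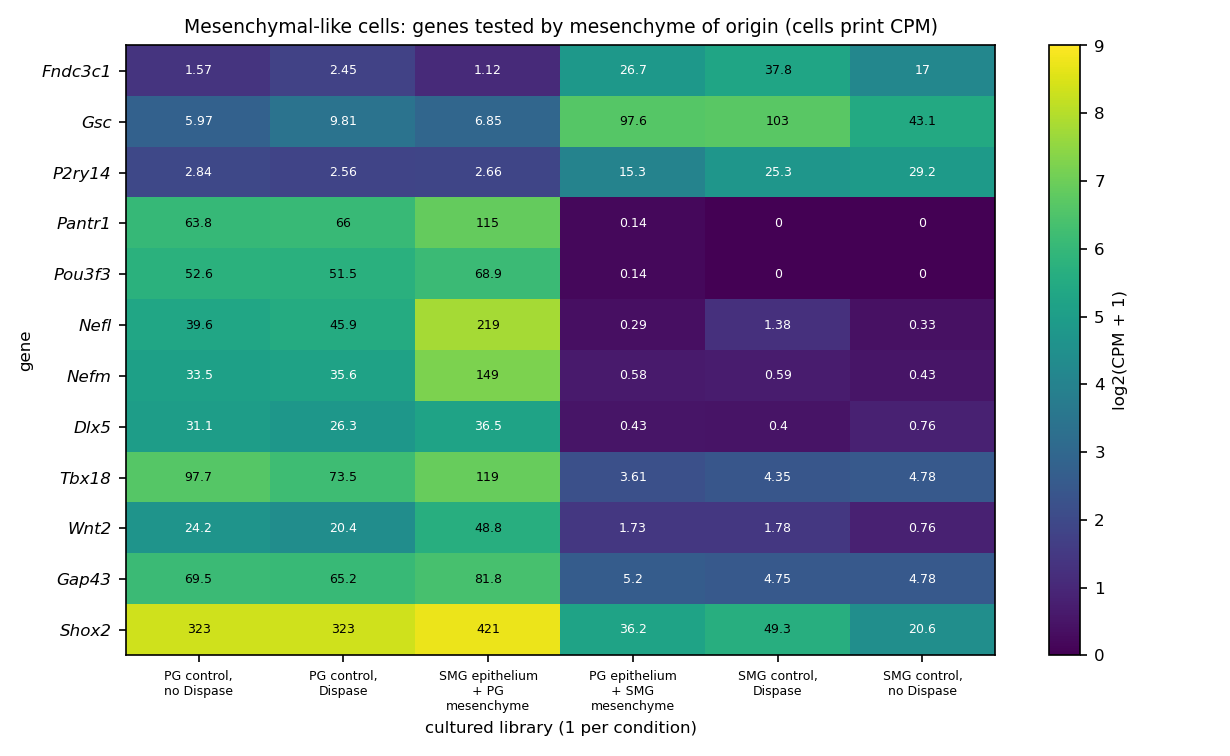
CPM of the genes tested by mesenchyme of origin in mesenchymal-like cells of each cultured library, printed in the cells and coloured by log2(CPM + 1). The 3 libraries of PG mesenchyme are on the left and the 3 of SMG mesenchyme on the right. Pou3f3 lies between 51.5 and 68.9 CPM with PG mesenchyme and at most at 0.14 CPM with SMG mesenchyme, and Gsc between 5.97 and 9.81 against 43.1 and 102.9 CPM.

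In epithelial-like cells a small set of genes, several of them secretory, differed by the gland that the epithelium came from. Counts were summed over all epithelial-like cells. Differences in the share of secretory (proacinar-like) cells were therefore not parted from differences within cells. Smgc was at 15486 CPM in SMG epithelium grown with PG mesenchyme and at 0.12 CPM in PG epithelium grown with SMG mesenchyme. This is a log2 difference by epithelium of origin of 14.19 (SE 0.65). Also higher with SMG origin was Prol1, a proline-rich secreted peptide of salivary and lacrimal gland (406 CPM in SMG epithelium with PG mesenchyme and no counts with PG origin, at least 664.5-fold; chromosome 5, 88317312 to 88328814). So were the secreted protein Pip (13.61, SE 1.06, 1 count on the low side), Tlx1 (at least 481.7-fold), Wfdc12 (7.71, SE 0.62) and Aldh1a7 (4.81, SE 0.40). BC037156 was higher with PG origin (-8.72, SE 0.68), and the T-box gene Tbx3 of the patterning list rose with SMG origin (5.22). Of 12 measured genes of the SMG and sublingual secretory list 2 rose over all genes tested and 6 adjusted over the list alone (median 3.33, also with the 1 member at 0 set to its bound), with Bpifa2 at 8.97. Of 7 genes of the parotid secretory list 2 rose over all genes tested and 7 adjusted over the list alone (median 8.97, also with 2 members at their bound), 3 of them shared with the first list. Of 20 genes of the acinar secretory machinery 9 rose adjusted over the list alone, such as the chloride cotransporter Slc12a2 (1.97) and Aqp5 (1.48). So did 5 of 7 mucous genes, such as the transcription factor Spdef (2.99), and 1 of 41 epithelial transcription factors, Foxa1 (4.30), none of these over all genes tested.

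With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7 genes were higher with SMG epithelium and 1 with PG epithelium of 13517 tested. By that edgeR quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.00206 for Smgc, 0.0287 for Prol1 and Tlx1 and 0.0195 for BC037156, each in 2 of 2 pairs. Leaving out 1 library gave 25 genes (PG epithelium with SMG mesenchyme), 115 (PG control without Dispase), 39 (PG control with Dispase), 45 (SMG control with Dispase), 20 (SMG epithelium with PG mesenchyme) and 104 (SMG control without Dispase). No gene passed when the Dispase term was left out. The levels of Smgc, Prol1 and Pip in the SMG control without Dispase (143, 0.31 and 0.06 CPM) lay far below those in the other SMG epithelia. Most epithelial-like cells were in clusters 3 and 5 for PG epithelium with SMG mesenchyme and in clusters 3, 6 and 8 for SMG epithelium with PG mesenchyme.

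**Figure D3:**
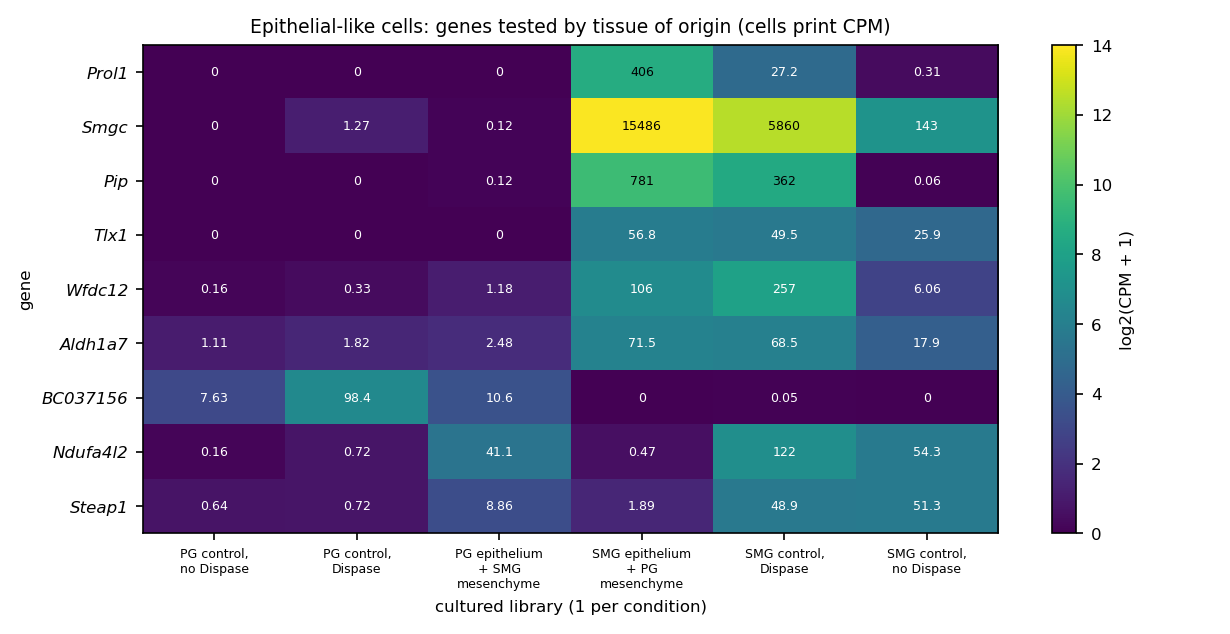
CPM of the genes tested by tissue of origin in epithelial-like cells of each cultured library, printed in the cells and coloured by log2(CPM + 1). The 3 libraries of PG epithelium are on the left and the 3 of SMG epithelium on the right. Smgc is at most at 1.27 CPM in PG epithelium and at 143 to 15486 CPM in SMG epithelium. Ndufa4l2 is at 41.1, 121.6 and 54.3 CPM in the cultures with SMG mesenchyme and at most at 0.72 CPM in those with PG mesenchyme.

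The origin of the mesenchyme was followed in epithelial-like cells by genes of low oxygen and sugar breakdown. Ndufa4l2 (chromosome 10, 127514967 to 127517154) was at 41.1 CPM in PG epithelium grown with SMG mesenchyme and at 0.47 CPM in SMG epithelium grown with PG mesenchyme, a log2 difference of 7.01 (SE 0.49). Steap1 differed by 4.43 (SE 0.35). Of 17 hypoxia and glycolysis genes 11 rose with SMG mesenchyme adjusted over the list alone and none over all genes tested, with a median of 1.40 above all random lists (-0.16 to 0.30). They include Ankrd37, a target of hypoxia-inducible factor (3.55), Slc2a1 (1.74), the mitophagy protein Bnip3 (1.81), Pgk1 (1.42) and the growth factor Vegfa (1.52). Of 35 mesenchymal ligands 2 fell adjusted over the list alone, the activin inhibitor Fst (-3.20) and the growth factor Pdgfa (-1.93). Of 11 basal and myoepithelial genes 2 fell, Krt5 (-2.66) and its regulator Trp63 (-1.99). Of 12 retinoic acid genes 3 fell, among them the retinoic acid receptor Rarb (-2.07), none of them over all genes tested. The interferon response list had 2 of 8 genes higher adjusted over the list alone, Isg15 (1.58) and Bst2 (1.97).

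By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 genes passed of 13517 tested, Ndufa4l2 (adjusted p 0.0311) and Steap1 (0.0403), in 2 of 2 pairs of libraries, and 888 had an unadjusted p under 0.05. Without 1 library the count was 17 (PG epithelium with SMG mesenchyme), 67 (PG control without Dispase) and 53 (PG control with Dispase). It was 167 (SMG control with Dispase), 15 (SMG epithelium with PG mesenchyme) and 60 (SMG control without Dispase). None passed under the stricter cell filter, the mitochondrial limits of 20% and 50% or classes assigned per cell, and DESeq2's Wald test passed 183.

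**Figure D4:**
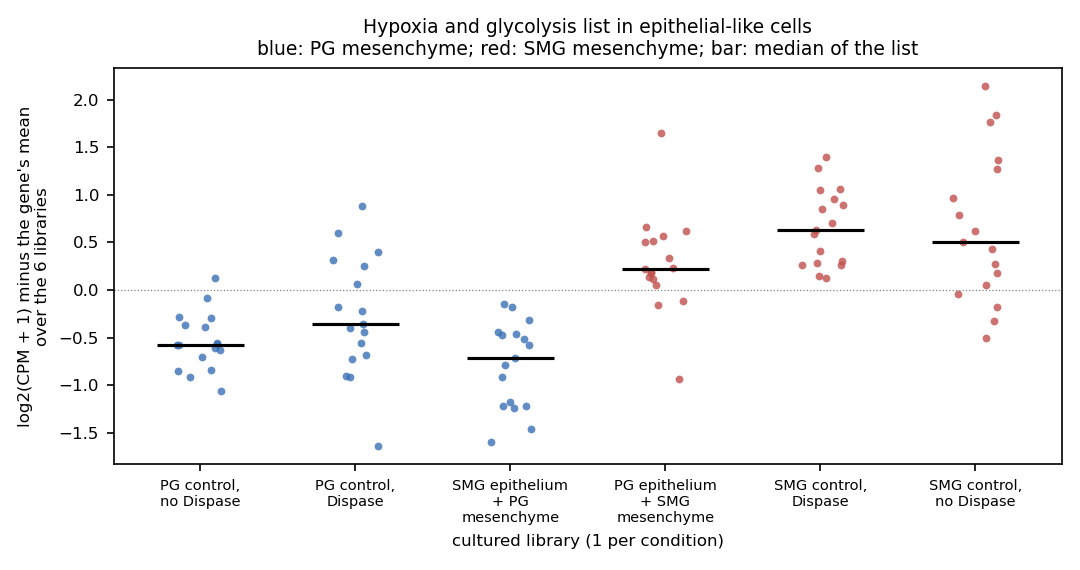
Level of 17 hypoxia and glycolysis genes in epithelial-like cells of each cultured library, as log2(CPM + 1) minus the gene's mean over the 6 libraries. There is 1 point per gene, a bar for the median of the list, blue for cultures with PG mesenchyme and red for those with SMG mesenchyme. The medians are -0.57, -0.36 and -0.71 with PG mesenchyme and 0.22, 0.63 and 0.50 with SMG mesenchyme.

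In mesenchymal-like cells the origin of the epithelium was marked by an epithelial secretory gene. Smgc (14.06, SE 0.66) was at 569 CPM in PG mesenchyme grown with SMG epithelium, 3.67% of its level in the epithelial-like cells of that culture. It was the only gene past the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p 0.0371, 2 of 2 pairs, 13565 tested). It is named although the rule against RNA of other cells leaves it out. Of 5 measured parotid secretory genes 4 rose adjusted over the list alone, among them Pip (10.48), Lpo, the peroxidase of saliva (6.64), and Bpifa2 (8.28). The mesenchymal ligands had a median of -0.42, below all random lists, with no member past either threshold. With 1 library left out the count was 17 (PG epithelium with SMG mesenchyme), 2 (PG control without Dispase), 13 (PG control with Dispase), 1 (SMG control with Dispase), 21 (SMG epithelium with PG mesenchyme) and 1 (SMG control without Dispase). No gene passed edgeR's quasi-likelihood test without the Dispase term, with a term for the Dispase-treated controls, under the stricter cell filter, under the mitochondrial limits of 20% and 50%, or with classes assigned per cell. With the full design 103 genes had an unadjusted p under 0.05, and DESeq2's Wald test passed 4.

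The Dispase comparison sets the 4 cultures coded as treated against the 2 untreated controls, and no gene passed in either class. It does not isolate the treatment, because the labels of the recombined cultures do not state it and the Dispase-treated controls stand apart from them. In epithelial-like cells 671 genes had an unadjusted p under 0.05 by edgeR's quasi-likelihood test and 67 passed DESeq2's Wald test. In mesenchymal-like cells the counts were 1238 and 170. Adjusted over the list alone, 7 of 12 interferon response genes were lower with Dispase in mesenchymal-like cells (median -1.86), among them Isg15 (-2.59) and Ifit3 (-2.61), antiviral proteins that stood at 489 CPM for Isg15 in the SMG control without Dispase and at 17.3 to 159 CPM elsewhere. In epithelial-like cells 3 of 8 interferon genes were lower on that adjustment (median -1.63). In the same cells 7 of 12 genes of the SMG and sublingual secretory list were higher (median 3.99), among them Smgc (4.92) and Bpifa2 (7.40), and 6 of 7 parotid secretory genes were higher (median 6.66, or 6.06 with the 1 member at 0 set to its bound). These secretory changes lean on the SMG control without Dispase, in which 4 of 2247 epithelial-like cells were proacinar-like and Smgc was at 143 CPM and Bpifa2 at 39.8 CPM, so they are not shown to come from Dispase. The near absence of proacinar-like cells holds only for cells within the main mitochondrial limit. Those 2247 cells held 15994969 UMIs. At a limit of 20% the epithelial-like cells of that library were 2703 with 34002442 UMIs. The cell cycle list had a median of 0.89 in epithelial-like cells, above all random lists. Without 1 library the epithelial count was 22 (PG epithelium with SMG mesenchyme), 296 (PG control without Dispase), 36 (PG control with Dispase), 2 (SMG control with Dispase), 22 (SMG epithelium with PG mesenchyme) and 1 (SMG control without Dispase). The mesenchymal count was 48, 0, 265, 4, 42 and 0 in the same order.

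PG epithelium grown with SMG mesenchyme, set against the Dispase-treated PG control, was higher in Ndufa4l2 (57.4-fold, 33.1 to 109, and 258-fold against the control without Dispase), the protease inhibitor Slpi (47.6-fold, 31.9 to 74.2) and the haem-degrading enzyme Hmox1 (31.2-fold, 25.5 to 38.4). Higher too were Ankrd37 (16.8-fold, 10.8 to 27.1), the chemokine Ccl20 (14.9-fold) and Bpifa2 (8.81-fold, 6.52 to 12.1). Against the control without Dispase Ankrd37 was 8.91-fold and Ccl20 5.55-fold higher. Bpifa2 was at 0.16 CPM in that control and at 26.2 CPM in the recombined culture. PG epithelium grown this way was lower in the basal keratins Krt15 (32.3-fold, 23.8 to 45.1) and Krt5 (27.96-fold, 20.3 to 39.6), in Txnip, a brake on glucose uptake (29.7-fold), and in Cbr2, a carbonyl reductase (27.9-fold). The hypoxia list had a median log2 ratio of 0.63, above all random lists. The ductal list (-1.43), the mesenchymal ligands (-1.39), the extracellular matrix list (-1.56) and the heat shock list (-1.29) lay below all of them. Another scaling (TMM) moves every log2 ratio of this pair by 0.39, so that single ratios stand low by that amount while the percentiles of lists do not move. As with the next 3 comparisons it is 1 library against 1, and the intervals cover counting error only. The Dispase-treated controls differ from the other libraries in the ways given with the interaction, whose cause is open. Against the controls without Dispase, over these comparisons together, 10 named genes kept within their intervals, 58 moved and 8 changed direction. Fold differences and list medians with no value for the control without Dispase are thus given against 1 control only.

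SMG epithelium grown with PG mesenchyme, against the Dispase-treated SMG control, was higher in Prol1 (14.9-fold, 13.9 to 16.1), the heat shock protein gene Hspa1a (20.2-fold), Fst (6.31-fold, 5.73 to 6.95, and 10.8-fold against the control without Dispase) and the alarmin Il33 (6.86-fold). Against the control without Dispase Hspa1a was 5.58-fold and Il33 3.71-fold higher. Smgc (2.64-fold) and Bpifa2 (2.39-fold), as list members, were also higher than with Dispase. The SMG control without Dispase held 143 CPM of Smgc, 39.8 CPM of Bpifa2 and 0.31 CPM of Prol1. This recombined epithelium held 15486, 9652 and 406 CPM. It was lower in Ndufa4l2 (257-fold, 87.8 to 1245, 3 counts in the recombined culture), Steap1 (25.8-fold, 14.8 to 50.1), the stress pseudokinase Trib3 (14.3-fold) and Try5 (at least 148-fold). The smooth muscle list (1.95), with the contractile genes Cnn1 (15.3-fold) and Acta2 (4.21-fold), the basal and myoepithelial list (1.78), the parotid secretory list (1.39) and the retinoic acid list (1.07) had medians above all random lists. An unnamed cluster led by the contractile genes Actg2 and Tagln held 18.5% of this culture and 0.091% of the control, and its RNA was not parted from the smooth muscle and myoepithelial lists. The hypoxia list (-1.30) lay below all of them.

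PG mesenchyme grown with SMG epithelium, against the Dispase-treated PG control, was higher in Spock3, a matrix proteoglycan (12.2-fold, 8.75 to 17.4), the troponin Tnnt2 (11.4-fold), Nefl (4.78-fold) and the tendon protein Tnmd (4.79-fold). It was lower in Slpi (19.9-fold), the acute phase protein Serpina3n (21.5-fold), the carbonic anhydrase Car3 (20.9-fold) and the hexokinase Hk2 (12.2-fold). Against the control without Dispase Spock3 was 4.13-fold, Tnnt2 2.14-fold and Tnmd 1.95-fold higher and Serpina3n 9.21-fold lower. The interferon list (-1.67), the adipogenic and osteochondrogenic list (-1.02), the end bud list (-0.91) and the FGF and ERK response list (-0.91) had medians below all random lists.

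SMG mesenchyme grown with PG epithelium, against the Dispase-treated SMG control, was higher in the collagen Col8a1 (65.4-fold, 22.2 to 319, 3 counts in the control), Fabp7, a fatty acid binding protein of glia (13.5-fold), the calcium-binding protein S100a4 (8.08-fold), the adhesion molecule Mcam (12.95-fold) and the matrix protein Aspn (6.80-fold). It was lower in the acute phase protein Saa3 (140-fold), the transferrin gene Trf (13.5-fold), the gelatinase Mmp9 (10.1-fold) and the retinoic acid binding protein Crabp1 (6.29-fold). Against the control without Dispase the differences were mostly smaller, at 2.34-fold for Col8a1, 3.93-fold for Mcam, 1.79-fold for Trf, 2.04-fold for Mmp9 and 1.21-fold for Crabp1. The smooth muscle list (1.25), the interferon list (1.32) and the cell cycle list (0.55) had medians above all random lists, but against the control without Dispase the interferon median was -1.12. The hypoxia list (-1.04) and the ductal list (-1.46) lay below all of them, and the neuronal and glial RNA list stood at 0.94 (percentile 99.94).

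How far each recombined tissue moved toward the other gland was measured over genes at least 2-fold apart between the controls without Dispase. Those genes' median change from the Dispase-treated control of the same gland was divided by their median difference between the Dispase-treated controls, which was only 0.51 in epithelium and 0.35 in mesenchyme on the log2 scale. On this scale 0 is no move and 1 is that difference, so a large share can be a small change, such as a median of 0.77 for PG epithelium. The share was 1.52 (1.48 to 1.59, over 893 genes) for PG epithelium with SMG mesenchyme and 0.53 (0.46 to 0.54) for SMG epithelium with PG mesenchyme. Under the stricter cell filter their order turned around, to 0.56 and 1.65. Over genes higher in PG and genes higher in SMG the shares were 1.76 and 0.86 for PG epithelium and 0.41 and 0.89 for SMG epithelium. With TMM scaling, chosen after the data were seen, the shares of all genes were 1.37 and 0.64, and by direction of gene 1.32 and 1.36 for PG epithelium and 0.53 and 0.71 for SMG epithelium. For mesenchyme it was 0.54 (0.47 to 0.64) for SMG mesenchyme with PG epithelium. It was -0.30 (-0.38 to -0.26) for PG mesenchyme with SMG epithelium. These pooled values hide unlike parts. Over the 551 genes higher in PG the shares were 0.32 and -0.064, and over the 279 higher in SMG they were 3.27 and -3.73, where the median gland difference was only 0.099. With TMM scaling the pooled values were 0.79 and -0.48. The intervals cover counting error only. Over the genes that differed between the glands at E13 the 2 epithelial shares were 0.027 and 0.29. With the same genes and the controls without Dispase as baseline, that of SMG epithelium turned to -0.38 (-0.52 to -0.12), and that of SMG mesenchyme went from 0.32 to 0.11. The shares thus depend on the cell filter, the scaling, the gland genes and the baseline, and the moves from Dispase-treated controls run along the split of those controls from the other cultures.

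The interaction of the 2 origins asks whether recombined cultures differ from what the origins add up to. In epithelial-like cells the interaction was positive for 14 genes and negative for 5 of 14322 tested. In mesenchymal-like cells it was positive for 30 and negative for 19 of 14309, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each value sums the log2 differences of both controls from both recombined cultures and is larger than a single log2 fold would be. The mitochondrial import gene Pam16 (13.21 in epithelium, 14.14 in mesenchyme) was among the genes with a positive interaction, and so was the histone gene Hist1h2ap (13.19) in epithelium. It was negative for the heat shock gene Hspa1a (-5.69 and -4.77), Arl6ip5, a membrane trafficking protein (-6.38 and -6.30), the chemokine Ccl20 in epithelium (-6.80) and S100a4 (-4.23) and Mcam (-6.08) in mesenchyme. Arl6ip5 was low only in the Dispase-treated controls, at 6.28 and 4.60 CPM in epithelial-like cells against 47.6 and 29.1 CPM in the controls without Dispase and 33.0 and 53.8 CPM in the recombined cultures. Hspa1a (54.2 CPM in epithelium) and Mcam (22.3 CPM in mesenchyme) in the PG control without Dispase also lay above their levels in PG epithelium with SMG mesenchyme (29.1 and 20.5 CPM). Crabp1 of the retinoic acid list had a positive interaction in mesenchyme (4.81). It was at 305 and 914 CPM in the PG controls, 262 and 1366 CPM in the SMG controls without and with Dispase, and 194 and 217 CPM in the recombined cultures. Adjusted over the list alone, 6 of 11 smooth muscle genes had a negative interaction in mesenchyme and 5 of 11 in epithelium. The unnamed contractile cluster held 18.5% and 11.1% of the recombined cultures, 8.72% and 2.47% of the PG and SMG controls without Dispase and at most 0.42% of those with Dispase, and its RNA was not parted from these values. Without the Dispase term 0 genes passed edgeR's quasi-likelihood test in either class, with 364 and 657 at an unadjusted p under 0.05, while DESeq2's Wald test of the full design passed 262 and 197. The stricter cell filter gave 719 and 13 genes and turned the interaction of Hspa1a in epithelium to 2.04.

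The control with Dispase of each gland stood apart from the other 4 cultures. Pam16 was at 107 and 110 CPM in the epithelial-like cells of these controls and at 0.64 to 0.95 CPM in the other 4 libraries. In both classes 12 genes, among them Pam16, Hist1h2ap and 7 genes of ribosomal proteins, were at least 8-fold apart between these 2 libraries and the rest. The count was 3 genes for the SMG control with Dispase together with SMG epithelium with PG mesenchyme and 0 genes for each of the other 13 pairs of libraries. The median mitochondrial share per barcode was 3.94% and 5.20% in these controls and 8.33% to 13.5% in the other 4. The interaction and the comparisons of recombined cultures with Dispase-treated controls run along this split. With a term for it 0 genes passed in epithelial-like and 6 in mesenchymal-like cells, while the main effects of origin are balanced across it.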

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

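Of the tests given here, the one of Dispase treatment and the term for the Dispase-treated controls were chosen only after the result was seen. The interaction of the 2 origins passed edgeR's quasi-likelihood test in 19 genes of epithelial-like cells and in 49 genes of mesenchymal-like cells. It passed in 0 and 0 genes without the Dispase term (364 and 657 at an unadjusted p under 0.05, and 262 and 197 by DESeq2's Wald test of the full design) and in 0 and 6 with a term for the Dispase-treated controls, so it is not shown that the origins fail to add up. Each recombined culture is 1 library. Pam16, BC004004, Hist1h2ap and Arl6ip5 follow the split between the Dispase-treated controls and the other 4 cultures, from which the interaction is hard to part.

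The pattern weighed is the 12 genes at least 8-fold apart between the 2 Dispase-treated controls and the other 4 cultured libraries in both classes, such as Pam16, Rpl10 and Rps27. A candidate explanation is that reads of near-identical gene copies were counted in another way in those 2 libraries. In the last 500 bases of their transcripts, 100% of the 12 genes share a stretch of 50 bases with another gene, against 83.3% at the upper end of random sets of like expression. Dispase treatment itself stays open. In 12 of 12 genes both recombined cultures lay nearer to the controls without Dispase. This cannot decide it, because the rule that picked the genes already set both recombined cultures apart from the Dispase-treated controls. The labels also do not say whether the recombined tissues were treated. The submitters' notes name the same tools for the 6 cultures, and no biological explanation was tested.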

How the results depend on the processing

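The mitochondrial limits of 20% and 50%, the Col9a1-led clusters taken into epithelium, the term for the 2 Dispase-treated controls, gland alone without 1 library, TMM scaling of the shares, and the controls without Dispase as comparators or baseline were chosen only after the result was seen. Counts of genes past the threshold stayed within 1.5 times in 49 values, went above in 60 and below in 34. Genes named in tested comparisons kept direction and side of the threshold in 769 values, missed the threshold in 260 and changed direction in 7. Of values between single libraries, genes kept within their intervals in 228, moved in 304 and changed direction in 8, list medians in 287, 70 and 9, and shares of the gland difference in 70, 65 and 3; shares of cells kept within their intervals in 60 and moved in 60. No paired analysis was possible because each condition is 1 library, with no second replicate number for the groups to share. The fit on proacinar-like cells alone was not run, because 3 libraries held 10 such cells or fewer. Depth is least in 3 cultures with 727, 818 and 1137 epithelial-like cells (SMG epithelium with PG mesenchyme, the PG control without Dispase, and PG epithelium with SMG mesenchyme), and 1 or 2 residual degrees of freedom limit all tests. Except where the number of genes tested, of cells or of libraries changed by construction, the cause was not tested for any value given here. The order of counts is control epithelium, then mesenchyme of origin, epithelium of origin, Dispase and interaction in epithelium, then the same 5 in mesenchyme, where the counts reported were 17, 2, 8, 0, 19, 89, 13, 1, 0 and 49 by edgeR's quasi-likelihood test.

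DESeq2's Wald test gave 471, 183, 101, 67, 262, 215, 190, 4, 170 and 197 genes in that order, and no filter on low counts gave 727, 86, 60, 28, 509, 750, 108, 6, 35 and 674. DESeq2 size factors gave 158 for the interaction in mesenchyme. The stricter cell filter gave 56 for control epithelium, 0 for mesenchyme of origin, 4 for epithelium of origin and 719 for the interaction in epithelium, and 34, 8, 0 and 13 in mesenchyme for control, mesenchyme of origin, epithelium of origin and interaction. The 20% mitochondrial limit gave 9 for control epithelium, 0 for mesenchyme of origin in epithelium, 36 for control mesenchyme and 0 for epithelium of origin in mesenchyme; the 50% limit, and classes assigned per cell, gave 0 for these same 2 origin comparisons. Taking in the Col9a1-led clusters gave 58 for control epithelium, 1 for mesenchyme of origin and 34 for the interaction. No doublet removal gave 145 for control mesenchyme and 120 for the interaction in mesenchyme. Without the Dispase term the counts were 0 for epithelium of origin and for the interaction in both classes and 7 for mesenchyme of origin in mesenchyme. With the term for the Dispase-treated controls they were 1, 3 and 0 in epithelium and 7, 0 and 6 in mesenchyme for mesenchyme of origin, epithelium of origin and interaction. With that term the log2 interaction turned to -0.94 for Pam16, -2.34 for Hist1h2ap and -0.63 for BC004004 in epithelium, and to -0.28 for BC004004, -1.32 for Bloc1s1 and -1.70 for Lbp in mesenchyme, and Hspa1a turned to 2.04 in epithelium under the stricter filter.

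With gland as the only term the controls gave 0 genes in both classes, and without 1 library (PG without Dispase, PG with Dispase, SMG with Dispase, SMG without Dispase) 0, 0, 1434 and 418 in epithelium and 2, 2, 1004 and 132 in mesenchyme. Leaving out 1 library of the 6 gave 15 to 167 genes for mesenchyme of origin, 20 to 115 for epithelium of origin and 1 to 296 for Dispase in epithelium, and 6 to 193, 1 to 21 and 0 to 265 in mesenchyme. A library left out leaves its condition empty, and the rest are assumed to vary alike.

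The share of the gland difference for PG epithelium with SMG mesenchyme was 1.52 and became 0.027 with E13 gland genes, 1.07 with 4-fold gland genes, 1.40 at 100 CPM or more, 1.65 with classes per cell, 0.56 with the stricter filter, 1.45 and 1.48 with the mitochondrial limits of 20% and 50%, 1.62 with the Col9a1-led clusters, 1.37 with TMM and 0.057 with E13 genes and controls without Dispase as baseline; over E13 genes higher in SMG it turned to -2.95. For SMG epithelium with PG mesenchyme it was 0.53 and became 0.29, 0.62 at 100 CPM, 1.65 with the stricter filter, 0.45 and 0.41 with those limits and 0.64 with TMM, and turned to -0.38 with E13 genes and the other baseline. For PG mesenchyme with SMG epithelium it was -0.30 and became -0.46 with 4-fold genes, -0.21 at 100 CPM and -0.51 with classes per cell. It was -0.39 with the 50% limit, -0.48 with TMM and -0.17 with E13 genes and the other baseline. There the share over genes higher in SMG was 0.52, but only because the median change (-0.077) and the median gland difference (-0.149) were both negative. For SMG mesenchyme with PG epithelium it was 0.54 and became 0.32 with E13 genes, 0.79 with TMM and 0.11 with the other baseline too.

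The median absolute log2 ratio over genes was 0.15 in E13 epithelium (0.13 with a pseudocount of 10) and 0.31 in E13 mesenchyme (0.32 without doublet removal, 0.29 with classes per cell, 0.30 with TMM and 0.26 with a pseudocount of 10). Against the Dispase-treated controls it was 0.52 for PG epithelium with SMG mesenchyme (0.47 with TMM, 0.42 with a pseudocount of 10, 0.33 against the control without Dispase), 0.39 for SMG epithelium with PG mesenchyme (0.40, 0.32 and 0.47), 0.32 for PG mesenchyme with SMG epithelium (0.27 with a pseudocount of 10 and 0.18 against the other control) and 0.37 for SMG mesenchyme with PG epithelium (0.37, 0.31 and 0.48).

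Against the controls without Dispase some log2 ratios changed sign. With these comparators named genes kept within their intervals in only 10 values, moved in 58 and changed direction in 8. List medians were alike in 23 values, moved in 23 and changed direction in 8. For PG epithelium with SMG mesenchyme Pam16 was 0.25, and the smooth muscle list median turned to -0.062 with classes per cell. For SMG epithelium with PG mesenchyme Pam16 was 0.21 and Hist1h2ap 2.56, and the medians of the acinar (1.66), mucous (1.93) and end bud (0.70) lists turned positive. For PG mesenchyme with SMG epithelium Pam16 was 0.24, Hist1h2ae 1.00 and Lbp 0.46, and the medians of the ductal list (0.32) and of the epithelial transcription factors (0.16) turned positive. For SMG mesenchyme with PG epithelium BC004004 was 0.33 and Bmp7 0.23, the medians of the mucous list (0.33) and of the epithelial transcription factors (0.14) turned positive, and that of the interferon list turned to -1.12. The cause was not tested. In the tested comparison by mesenchyme of origin in epithelium, the hypoxia and glycolysis median was 1.40, and 1.41 with DESeq2 size factors. Medians of other lists in tested comparisons are given under the main scaling only.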

Other observations

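Of the tests given here, those of Smgc RNA, of the medians within sets of libraries, of the extracellular matrix list and of other splits of the libraries were chosen only after the result was seen. Many, but not all, of the genes that told the glands apart at E13 kept their direction in culture, which was not tested against chance. In epithelium 37 of 55 such genes (67.3%) had the same direction between the controls without Dispase and 45 of 64 (70.3%) between those with Dispase, and in mesenchyme 300 of 438 (68.5%) and 365 of 462 (79.0%). Among those at least 2-fold apart in culture, 24 kept their direction and 16 turned around in epithelium without Dispase, 22 and 9 with Dispase, and 151 and 38, and 110 and 14, in mesenchyme. Foxa1 was higher in SMG epithelium at E13 and stood at 13.1 and 44.2 CPM in the SMG controls without and with Dispase against 0.48 and 3.86 CPM in the PG controls. Ndufa4l2 turned around, being 7.56-fold higher in PG epithelium at E13 and higher in SMG epithelium in culture, by 7.79 on the log2 scale.

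At E13 the mesenchyme of the glands held unlike shares of other cells. Skeletal muscle-like cells, which expressed Myog and Actc1, were 5.36% (4.87 to 5.89%) of PG mesenchyme against 0.931% (0.751 to 1.14%), pericyte or smooth muscle-like cells 3.71% against 0.739%, and endothelial-like cells 3.02% against 1.40%, all higher in PG. Erythroid-like cells (0.502% against 0.769%) and neuronal-like cells (0 of 7572 against 77 of 9878) were higher in SMG. In culture an unnamed cluster led by the contractile genes Actg2, Tagln and Mylpf held 18.5% of the cells of SMG epithelium with PG mesenchyme, 11.1% of PG epithelium with SMG mesenchyme, 8.72% of the PG control without Dispase, 2.47% of the SMG control without Dispase and at most 0.42% of the Dispase-treated controls. Another, led by the neutrophil genes S100a8 and S100a9 and by Saa3, held 14.7% of the SMG control without Dispase and at most 0.169% of any other culture, and a cluster led by the fat cell genes Adipoq and Fabp4 held 0.881% of the PG control with Dispase. These clusters were not named by the marker rule, and each condition is 1 library.

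Hypoxia and glycolysis genes were higher in epithelial-like cells grown with SMG mesenchyme, and the question is whether a technical difference accounts for it. The list median was 0.84 within the 2 Dispase-treated controls and 1.13 within the other 4 libraries, so the split between those sets of libraries does not carry it. Within the 2 controls epithelium and mesenchyme differ together, so 0.84 does not tell their origins apart. Within the other 4 libraries each epithelium stood with both mesenchymes. With 1 library left out the lowest median was 1.35 (without the SMG control with Dispase) and the highest 1.54, which argues against any 1 library. More RNA from mesenchymal cells would raise matrix genes, and the extracellular matrix list stood at -0.58. Hypoxia genes also rose in SMG control mesenchyme, so a like amount of its RNA in every culture could carry such a difference. The matrix list cannot tell this. As a hypothesis found on the same data and not decided by these tests, the SMG mesenchyme may itself set the state of the epithelium. A difference in size or oxygen supply of the cultures was not tested, and the rise in SMG control mesenchyme leaves it open.

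Smgc counts in mesenchymal-like cells of cultures with SMG epithelium are a candidate for RNA from epithelial cells. The mesenchymal level was 3.67% of the epithelial level in SMG epithelium with PG mesenchyme, where epithelial markers ranged from 1.63% to 5.31%, and 5.19% in the SMG control with Dispase, where they ranged from 6.46% to 16.9%. The first value lies within the range of the markers and the second below it, so the test leaves the question open. Bpifa2 (3.48% and 4.28%) gives the same picture, while Pip (7.03% and 5.79%) and Prol1 (6.54% and 3.64%) lie above the range of the markers in the first culture and below it in the second. Expression by mesenchymal cells, and epithelial cells placed in the mesenchymal class, were not tested.

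Other splits of the 6 libraries into 3 and 3 gave 10 arrangements, of which 9 could be fitted, and a share of 10 splits cannot go under 0.05. For mesenchyme of origin in epithelium the real split called 2 genes and the highest other 2, so 2 of the 9 gave as many. For epithelium of origin in epithelium the real split called 8 and the highest other 0, for mesenchyme of origin in mesenchyme 13 and 0, and for epithelium of origin in mesenchyme 1 and 0, with 1 of the 9 splits reaching the value each time.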
